A study of Mus musculus with 20 samples.

How the data were processed

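Gene expression was measured in uterine natural killer (NK) cells sorted by flow cytometry from the utero-placental tissue of 20 pregnant mice at gestation day 10.5. The series text gives day 10.5 for every pregnancy and was followed; the sample descriptions print a day whose decimals count up by 1 from sample to sample, in 2 runs of 10 that start at 10.5, which was taken for a copying error. Per the labels, female C57BL/6J mice were put at 9 weeks of age on a diet rich in fat and sucrose, or on a matched control diet low in fat and free of sucrose, for 13 weeks before pregnancy and throughout it. The labels sort the mice into 3 groups of separate animals: 10 control mice, 6 mice that became obese on the high-fat diet (obese) and 4 mice on the same diet called resistant to obesity (obese resistant). The labels do not give the weights or the criterion that separated the obese from the obese-resistant mice. Total RNA with an integrity number above 8 was labelled with biotin and hybridised by the authors to whole-transcript Affymetrix arrays, with 1 array per mouse.

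The deposited values are log2 probe set intensities, and the authors made them with the R package oligo, for which neither the version nor the background correction, normalization and summarization methods are stated. The values were used as deposited, without a further scaling. Array data hold no counts, so the number of arrays limits the precision. The genome build behind the probe sets is not stated, so no coordinates are given, and genes are identified by symbol and Entrez number.

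The table holds 29129 probe sets. Of these, 19572 carried 1 gene symbol, 0 carried several and 9557 carried none, which includes 377 control probe sets. For the 55 symbols with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 19505 genes. A gene was tested when its value exceeded the median of the whole table, 6.48, in at least 4 arrays, the size of the smallest group, and 11867 genes met this. Probe sets of close paralogs, such as those of the Ly49 receptors and the granzymes, can share sequence, so their values are not independent.

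Each gene was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a mean for each of the 3 groups and 1 spread shared by all groups. There were 4 comparisons: obese versus control, obese resistant versus control, obese versus obese resistant, and high-fat diet versus control, the last as the mean of both high-fat group means minus the control mean. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, with a threshold of 0.05. The labels give no batch and no pairing of mice.

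For each comparison, the passing genes were to be named, and where fewer than 10 passed, the 6 genes with the smallest p among those higher and the 6 among those lower were named as genes that did not pass. From each gene list described, up to 4 members with the smallest p were named. For obese versus control, 10 genes were named whatever their values: Ncr1, Eomes, Itga1, Itga2, Prf1, Gzmb, Ifng, Vegfa, Pgf and Klrg1.

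The 37 gene lists were written from general knowledge and not from these arrays. They cover NK identity, the conventional NK subset, the tissue-resident NK and ILC1 subset, Ly49 receptors, activating receptors and adaptors, inhibitory receptors, the cytotoxic granule, NK cytokines and chemokines, angiogenic factors, extracellular matrix and its remodelling, the TGF-beta pathway, the hypoxia response, glycolysis, oxidative phosphorylation, fatty acid oxidation and lipid handling, cholesterol synthesis, fatty acid synthesis, the cell cycle, the interferon response, inflammatory and NF-kB genes, insulin, leptin and adipokine signalling, and the unfolded protein response. A pair of lists served as technical checks: ribosomal proteins, and genes induced by tissue dissociation together with immediate early genes. The markers of other cells that the sort could hold were those of decidual stromal cells, trophoblast and fetal cells, endothelial cells, smooth muscle cells and pericytes, epithelial cells, macrophages and monocytes, dendritic cells and MHC class II, neutrophils, T cells, B cells, erythroid cells, platelets and megakaryocytes, and mast cells and basophils. The 35 lists with at least 5 tested genes were tested with camera from limma at its preset inter-gene correlation of 0.01. Camera compares the mean test statistic of a list's genes with that of all other tested genes. Adjustment was over the 35 lists of a comparison. The B cell list, with 2 tested genes, and the platelet list, with 4, were too short to test. Camera was run again with the correlation estimated for each list, and fry from limma was run as a test of each list on its own. A call of a list means an adjusted p under 0.05 with the preset correlation.

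These groups, comparisons, tests, lists and naming rules, and most alternatives, were chosen before the data were examined. The alternatives changed the filter on dim genes (none, or a stricter one at the 70th percentile of the table), the scaling (quantile normalization again, or each array shifted to 1 median), the variance model, the weights of arrays, the groups in the fit, the threshold and the probe sets tested. Others used each of the 2 numbers in the sample titles, whose meaning the labels do not give, as a block or a covariate, added the mean of the decidual stromal or of the macrophage markers to the fit, or left out each array in turn.

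A split of the arrays was seen in the values and was not chosen beforehand. The 11 arrays whose first title number was 18 or lower are called the first array set, and the 9 arrays with 20 or higher the second array set. Every comparison was then repeated with the array set as a block in the fit and within each set. The second set holds 1 obese array, which is assumed there to vary like the arrays of the other groups. Mean log2 signals of 3 kinds of control probes were compared between the sets with exact permutation tests over all 167960 regroupings of the arrays, with Python 3.11.15 and NumPy 2.4.6. Figures were drawn with matplotlib 3.10.9.

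The fit was tested on simulated data with the spread and the array set difference of these arrays, no group effect, and 50 genes changed by each of 4 folds. Genes were drawn independently of each other, and the genes of all 4 folds were changed together. The recovery rates hold for that setting only, and could be lower where fewer genes change or genes vary together. In obese versus control, it recovered 34% of the genes changed 1.5-fold, 70% of those changed 2-fold, 88% at 3-fold and 96% at 4-fold, with 14 false calls among all genes. For genes changed 2-fold, the recovery was 72% in obese resistant versus control, 60% in obese versus obese resistant and 88% in high-fat diet versus control. Group labels were also redrawn 100 times for each comparison to count how often other splits of the same arrays gave as many genes or lists. Labels were redrawn within the array sets as well, 100 times or, for obese versus obese resistant, over all 63 possible splits, to see what the set imbalance alone calls and to test the counts with the block.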

Results

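Uterine NK cells, the lymphocytes that gather around the implantation site in early pregnancy, were profiled on 20 arrays from 20 mice. The groups were 10 control mice, 6 obese mice and 4 obese-resistant mice, each of the last 10 on the high-fat, high-sucrose diet. Array medians lay between 6.35 and 6.61 on the log2 scale. Pairs of arrays correlated at 0.906 to 0.988 across probe sets, and no 2 arrays were identical.

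The arrays fell into 2 sets, over which the groups were spread unevenly. The first principal component held 45.6% of the variance, against 9.25% for the next, and its score ran from -51.4 to -9.42 in the 11 arrays of the first set and from 25.1 to 36.6 in the 9 arrays of the second. The first set held 4 control, 5 obese and 2 obese-resistant mice, and the second held 6, 1 and 2. Between the sets, 6009 of 11867 genes differed in limma with the groups in the fit, 4092 higher and 1917 lower in the second set; the balance depended on the scaling, with 2926 and 2847 after cyclic loess and 5448 and 1157 with arrays shifted to 1 median. Lgals3, which codes for galectin-3 and was named after its value was seen, was higher by 2.33 in the second set, and Stac3, also named afterwards, differed by -1.19. The median difference over all tested genes was 0.14, while the array medians averaged 6.54 in the first set and 6.40 in the second. Genes of decidual stromal cells had a median difference of 0.80, those of the cell cycle 0.57, oxidative phosphorylation 0.40 and NK identity -0.06. Since most obese mice were in the first set and most controls in the second, values with the array set as a block and within each set are printed beside the results. This holds for the lists, the top-ranked genes and the genes given whatever their values. Members named for a list are given without the block unless stated, so their differences can include the set difference.

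**Figure D1:**
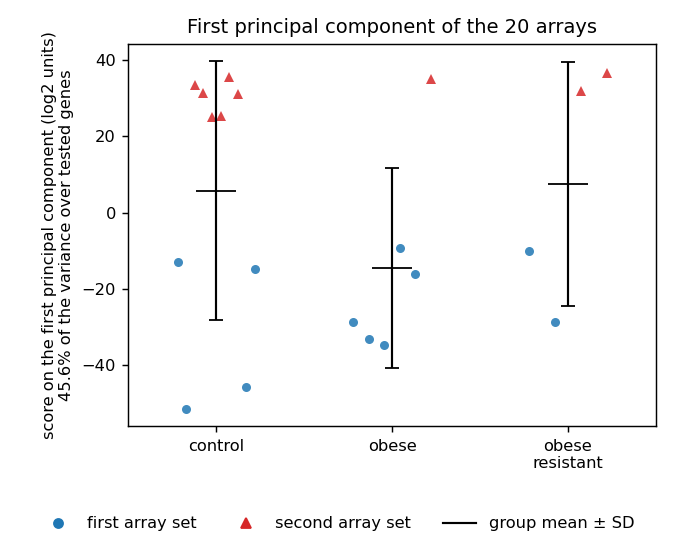
Score of each of the 20 arrays on the first principal component (vertical axis, log2 units) by group, with circles for the first array set, triangles for the second, and the group mean with its SD. Arrays of the second set lie at 25.1 or higher and those of the first at -9.42 or lower in every group.

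The comparison of obese with control mice asks how diet-induced obesity was associated with gene expression in uterine NK cells. No single gene passed, and the genes nearest to passing differed by less than 2-fold. Homer3, a scaffold protein (Entrez 26558), averaged 6.62 ± 0.29 in obese mice (SD, n = 6) and 5.94 ± 0.37 in control mice (SD, n = 10). Irf4, a transcription factor of activated lymphocytes (Entrez 16364), averaged 6.70 ± 0.14 in obese and 6.22 ± 0.22 in control mice. Both genes are dim: their control means lay below the table median of 6.48 used as the filter. They passed that filter mostly through obese arrays. Hmgn1, a nucleosome-binding protein (Entrez 15312), averaged 6.78 ± 0.18 in obese and 7.26 ± 0.23 in control mice.

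The 6 highest-ranked genes with higher values in obese mice were Slc25a36, a mitochondrial nucleotide carrier (0.67 ± 0.16, log2 difference ± SE), Homer3 (0.69 ± 0.16), Taf1c, a subunit of an initiation factor for ribosomal RNA genes (0.48 ± 0.12), Irf4 (0.48 ± 0.12), Lbh (0.44 ± 0.12) and Il18rap, a cytokine receptor subunit (0.74 ± 0.21). All 6 obese mice exceeded the control mean for each of them except Il18rap, where 5 did. With the array set as a block the differences were 0.62, 0.63, 0.45, 0.43, 0.43 and 0.49. Within the first set they were 0.97, 0.49, 0.42, 0.53, 0.47 and 0.80. Against the second set's controls, its 1 obese mouse differed by -0.11 for Slc25a36, -0.13 for Il18rap and 0.28 to 0.89 for the other 4. The 6 highest-ranked genes with lower values were Hmgn1 (-0.49 ± 0.12), Prr14l (-0.51 ± 0.14), Pcgf2, a polycomb protein (-0.95 ± 0.26), Ccdc148 (-0.68 ± 0.19), Scp2, a sterol carrier protein (-0.72 ± 0.20), and Gm3448 (-0.66 ± 0.19). All 6 obese mice lay below the control mean for these except Pcgf2, with 5. With the block the differences were -0.37, -0.35, -0.55, -0.58, -0.52 and -0.61, and each was also negative within both sets.

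With limma, 0 of 11867 genes passed in obese versus control (smallest adjusted p = 0.822). An unadjusted p under 0.05 was found for 499 genes, 232 higher and 267 lower. Evenly spread p-values would give 593. Splits of the same mice into other groups had a median of 352, and 38 of 100 splits, the real one included, gave at least 499. Chance is therefore not excluded for this count. With the array set as a block 0 genes passed and 353 had an unadjusted p under 0.05, and 0 passed within either set. Weights estimated for each array gave 1783 passing genes, and such weights together with the block gave 0. The median 95% confidence interval of a gene reached 0.37 to either side, and for 91.6% of genes it lay within 2-fold in both directions.

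**Figure D2:**
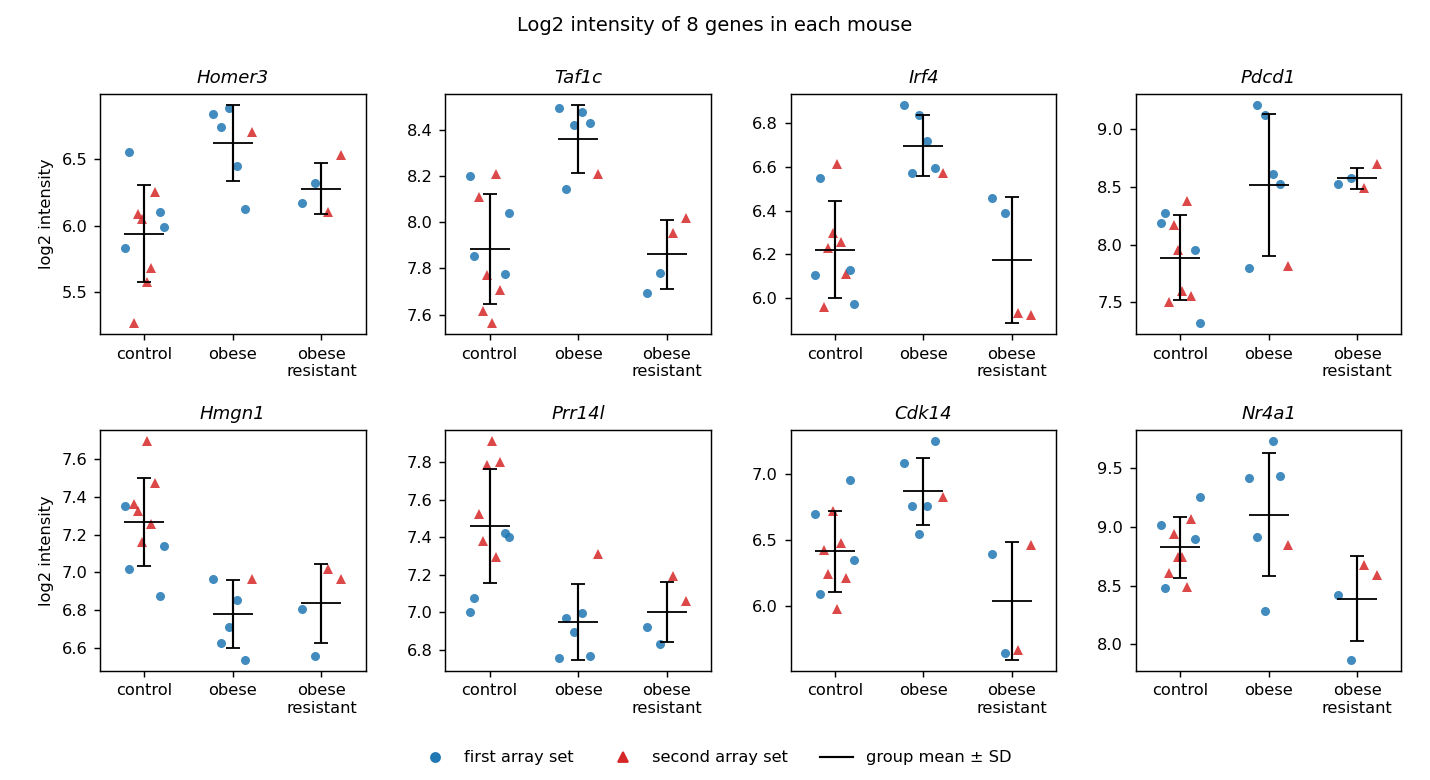
Log2 intensity (vertical axis) of 8 genes in each mouse by group, with circles for the first array set, triangles for the second, and the group mean with its SD. None of the 8 passed the test over all genes in any of the 4 comparisons, and Hmgn1 lay below the control mean in 10 of 10 mice on the high-fat diet.

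Among the genes given whatever their values, the differences between obese and control mice ran from -0.16 (Vegfa) to 0.34 (Itga2). That a gene did not pass does not show that it was unchanged. The log2 differences were -0.13 ± 0.16 (SE) for Ncr1, an activating receptor, -0.02 ± 0.15 for Eomes, a transcription factor of NK cells, 0.34 ± 0.20 for the integrin Itga2 and -0.13 ± 0.15 for the receptor Klrg1. Perforin (Prf1) differed by -0.11 ± 0.15, granzyme B (Gzmb) by 0.00 ± 0.13 and interferon gamma (Ifng) by 0.25 ± 0.23. The vessel growth factors Vegfa and Pgf differed by -0.16 ± 0.16 and 0.13 ± 0.23. None passed, and no named probe set was found for Itga1. With the block these 9 differences lay between -0.23 (Vegfa) and 0.16 (Gzmb), within the first set between -0.16 (Klrg1) and 0.29 (Pgf), and for the 1 obese mouse of the second set between -0.72 (Vegfa) and 0.24 (Ifng).

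As groups, 9 of the 35 gene lists were called in obese versus control, 3 higher and 6 lower, and none of their members passed when adjusted over the list alone. No list was called with an estimated correlation: the adjusted p was 0.662 for the ribosomal proteins and 0.609 for each of the other 8. By fry the smallest adjusted p was 0.585. With the array set as a block 2 lists were called, cholesterol synthesis and the interferon response, and neither was with an estimated correlation as well (adjusted p = 0.896 for each).

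Genes of cholesterol synthesis were lower in obese mice as a group (median log2 difference -0.30, 17 of 17 genes lower, adjusted p = 8.39e-05 by camera; adjusted p = 0.609 with an estimated correlation). Their mean was 8.72 ± 0.32 in obese mice (SD, n = 6) and 9.03 ± 0.31 in control mice (n = 10), and 5 of 6 obese mice lay below the control mean. Sqle, squalene epoxidase, differed by -0.52 ± 0.21 (SE), Fdps, farnesyl diphosphate synthase, by -0.65 ± 0.27, Lss, lanosterol synthase, by -0.41 ± 0.18 and Mvk, mevalonate kinase, by -0.37 ± 0.18, none of them passing alone. With the block the list had a median of -0.23, with 5 of 17 genes higher (adjusted p = 0.0129). Within the first set the median was -0.31, and the 1 obese mouse of the second set gave 0.11. The call held without any 1 array, and the median was -0.46 without obese mouse 6.

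Interferon response genes were higher as a group (median 0.14, 17 of 23 genes higher, adjusted p = 0.0146; adjusted p = 0.609 with an estimated correlation). Their mean was 7.74 ± 0.27 in obese (SD, n = 6) and 7.62 ± 0.24 in control mice (n = 10), with 3 of 6 obese mice above the control mean. Oasl1 differed by 0.57 ± 0.24, Ifit1 by 0.45 ± 0.20 and Mx2 by 0.37 ± 0.18. With the block the median was 0.21 (adjusted p = 0.00785); it was 0.31 within the first set and -0.07 in the second. The call ended without obese mouse 1 (adjusted p = 0.206), control mouse 1 (0.137) or obese mouse 4 (0.0748), with medians of 0.06, 0.08 and 0.09.

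Genes of the cell cycle and of oxidative phosphorylation were lower as groups, and these calls ended with the block. For the cell cycle 29 of 30 genes were lower, with a median of -0.29 (adjusted p = 0.000315, and adjusted p = 0.609 with an estimated correlation), among them Kif11 (-0.44 ± 0.17), Bub1 (-0.43 ± 0.23) and Cenpf (-0.29 ± 0.15). With the block the median was 0.00 (adjusted p = 0.689), and it was -0.02 in the first set and 0.16 in the second. Oxidative phosphorylation genes were lower in 33 of 35 cases, with a median of -0.17 (adjusted p = 0.000361, and adjusted p = 0.609 with an estimated correlation), among them Uqcrq (-0.47 ± 0.25) and Ndufa1 (-0.37 ± 0.20). The median with the block was -0.02 (adjusted p = 0.299), -0.05 in the first set and 0.07 in the second. In both lists 5 of 6 obese mice lay below the control mean. Both calls held without any 1 array, while the median was -0.18 without obese mouse 2 for the cell cycle and -0.25 without control mouse 2 for oxidative phosphorylation.

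Lists that stand for subsets or other cells also moved with the group. Tissue-resident NK and ILC1 genes had a median of 0.20 (9 of 12 higher, adjusted p = 0.0175), with Inpp4b at 0.71 ± 0.33 and Tnfsf10 at 0.43 ± 0.20; the block gave 0.09 (adjusted p = 0.539), and the sets 0.13 and -0.01. This call ended without obese mouse 1 (adjusted p = 0.150), obese mouse 4 (0.0748) or control mouse 3 (0.0655), with medians of 0.04, 0.11 and 0.10. T cell markers had a median of 0.20 (9 of 10 higher, adjusted p = 0.0146), with Cd8a at 0.62 ± 0.31 and Cd3e at 0.48 ± 0.27. The block gave 0.19 (adjusted p = 0.443), the sets gave 0.20 and 0.05, and the call ended without obese mouse 1 (adjusted p = 0.227). Decidual stromal markers had a median of -0.23 (16 of 17 lower, adjusted p = 0.0278), with Nr2f2 at -0.87 ± 0.41 and Hoxa11 at -0.42 ± 0.24, and the block gave 0.05 (adjusted p = 0.945). Trophoblast and fetal markers had a median of -0.36 (7 of 7 lower, adjusted p = 0.0278), with Peg10 at -0.57 and Igf2 at -0.33, and the block gave -0.21 (adjusted p = 0.282). Ribosomal protein genes had a median of -0.11 (21 of 23 lower, adjusted p = 0.0278), with Rpl23 at -0.29 and Rps15a at -0.25, and the block gave 0.03 (adjusted p = 0.945). Within the first and second sets the medians were 0.04 and -0.06 for decidual, -0.20 and -0.07 for trophoblast, and 0.06 and -0.04 for ribosomal genes. Of the 20 fits without 1 array, 7 ended the decidual call, 6 the trophoblast call and 4 the ribosomal call; the adjusted p reached 0.146 for decidual and 0.124 for trophoblast markers (each without obese mouse 4) and 0.0823 for ribosomal genes (without obese mouse 1). Medians that moved by over 1.5 times were 0.11 without obese mouse 1 and 0.30 without obese mouse 3 for T cell, -0.22 without obese mouse 3 and -0.20 without control mouse 5 for trophoblast and -0.07 without obese mouse 3 and -0.18 without control mouse 9 for ribosomal genes.

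**Figure D3:**
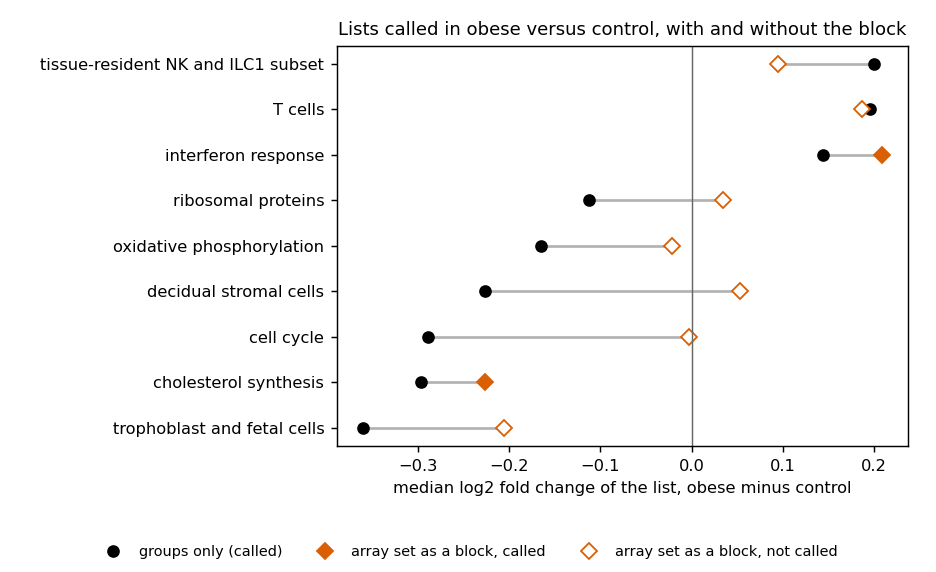
Median log2 difference between obese and control mice (horizontal axis) of the 9 lists called in that comparison, without the array set in the fit (circles) and with it as a block (diamonds, filled where called). Cholesterol synthesis (-0.30 and -0.23) and the interferon response (0.14 and 0.21) were called both ways, though not with an estimated correlation (adjusted p = 0.609 without and 0.896 with the block), and the cell cycle median went from -0.29 to 0.00.

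The other 26 lists were not called in obese versus control. Their medians are followed in brackets by those with the block, in the first set and for the 1 obese mouse of the second set. Among NK functions they were 0.06 (0.03, 0.08 and -0.08) for NK identity, 0.25 (0.18, 0.24 and 0.05) for the conventional NK subset, -0.02 (-0.04, 0.11 and -0.29) for Ly49 receptors, whose test pointed up, -0.06 (0.05, 0.13 and -0.03) for activating receptors and adaptors, 0.08 (0.05, 0.08 and -0.05) for inhibitory receptors, -0.06 (0.06, 0.06 and -0.04) for the cytotoxic granule and 0.13 (0.11, 0.14 and -0.03) for NK cytokines and chemokines. For tissue and vessel factors they were -0.07 (0.03, 0.05 and -0.07) for angiogenic factors, -0.05 (0.04, 0.04 and 0.00) for extracellular matrix, 0.11 (0.15, 0.20 and -0.07) for the TGF-beta pathway and -0.14 (-0.03, -0.02 and 0.02) for the hypoxia response. For metabolism and stress they were -0.09 (0.09, 0.14 and 0.07) for glycolysis, whose mean was 0.01, -0.04 (0.15, 0.17 and 0.03) for fatty acid oxidation, whose test pointed up, -0.14 (0.01, -0.11 and 0.12) for fatty acid synthesis, 0.04 (0.02, 0.05 and -0.13) for insulin, leptin and adipokine signalling, -0.07 (0.01, 0.05 and -0.05) for the unfolded protein response, 0.13 (0.17, 0.16 and -0.28) for inflammatory genes and 0.00 (0.07, 0.12 and -0.12) for dissociation and immediate early genes. For other cells they were -0.09 (0.21, 0.19 and 0.22) for endothelial, -0.30 (-0.06, -0.07 and 0.07) for smooth muscle, -0.09 (-0.01, -0.18 and 0.09) for epithelial, 0.10 (0.05, 0.33 and -0.90) for macrophage, 0.15 (0.08, 0.35 and -0.77) for dendritic cell, 0.41 (0.36, 0.86 and -0.48) for neutrophil, -0.27 (-0.06, 0.38 and -1.75) for erythroid and 0.16 (0.22, 0.40 and -0.54) for mast cell markers. The sign turned with the block for activating receptors, the cytotoxic granule, angiogenic factors, extracellular matrix, glycolysis, fatty acid oxidation, fatty acid synthesis, the unfolded protein response and endothelial markers. Members with the smallest p included Fads2 (-0.78) and Scd1 (-0.74) of fatty acid synthesis, Hk2 (0.57) of glycolysis, Pdgfa (-0.58) of angiogenic factors and Stx11 (-0.57) of the cytotoxic granule.

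The comparison of obese-resistant with control mice asks what differed in mice that ate the same diet without becoming obese. Pdcd1, which codes for the inhibitory receptor PD-1 (Entrez 18566), averaged 8.58 ± 0.09 in obese-resistant mice (SD, n = 4) and 7.89 ± 0.37 in control mice (SD, n = 10), and Dclre1a, a DNA crosslink repair nuclease (Entrez 55947), averaged 6.89 ± 0.21 and 7.51 ± 0.28. These and the other top genes did not pass. Those with higher values were Rgs18 (0.58 ± 0.18, SE), Slc9a7 (0.57 ± 0.19), Wrnip1 (0.59 ± 0.20), Pdcd1 (0.69 ± 0.24), Fgl2 (0.36 ± 0.13) and Prkar2b (0.65 ± 0.24). Those with lower values were Dclre1a (-0.62 ± 0.18), Otx1 (-0.41 ± 0.13), Slx4ip (-0.71 ± 0.23), Acot1 (-0.52 ± 0.17), Hmgn1 (-0.43 ± 0.14) and Prr14l (-0.46 ± 0.16). All 4 obese-resistant mice lay on that side of the control mean for each of them except Acot1, with 3. With the block the differences were between 0.36 and 0.67 for the former and between -0.70 and -0.40 for the latter, and each kept its sign within both sets.

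Genes induced by dissociation and immediate early genes, the one list called, were lower as a group in obese-resistant mice (median -0.14, 16 of 21 genes lower, adjusted p = 0.000627 by camera; adjusted p = 0.890 with an estimated correlation). Their mean was 9.34 ± 0.24 in obese-resistant (SD, n = 4) and 9.52 ± 0.19 in control mice (n = 10), and 4 of 4 lay below the control mean. Hspa1b, a heat shock protein, differed by -0.49 ± 0.24 (SE) and Nr4a1, a nuclear receptor induced by activation, by -0.44 ± 0.21. The median with the block was -0.14 (adjusted p = 0.00237), and within the sets -0.08 and -0.12. Without obese-resistant mouse 2 the median was -0.03 and the call ended (adjusted p = 0.324); without control mouse 8 the median was -0.04. Cholesterol synthesis had a median of 0.00 and a mean of 0.00, with 8 of 17 genes higher, and the cell cycle had a median of 0.01. With limma, 0 of 11867 genes passed (smallest adjusted p = 0.9998, 83 with an unadjusted p under 0.05, 261 with the block), and array weights also gave 0. None of the members of any list passed when adjusted over the list alone.

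**Figure D4:**
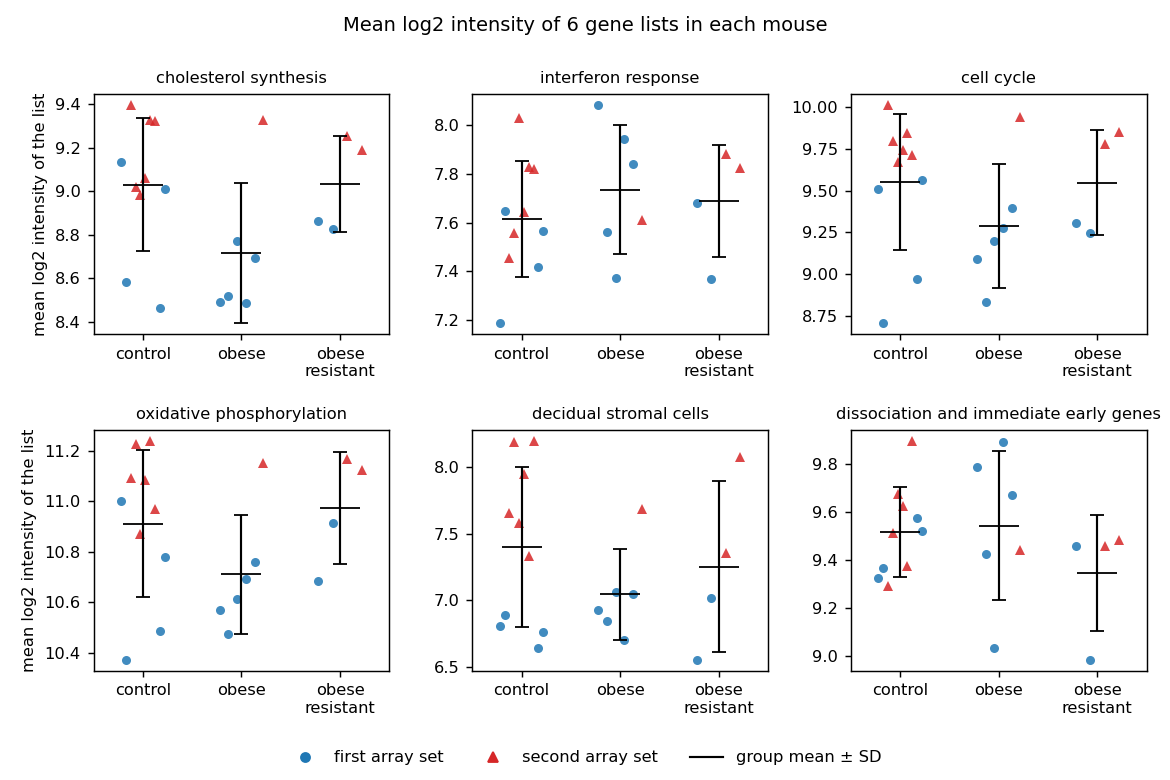
Mean log2 intensity (vertical axis) of 6 gene lists in each mouse by group, with circles for the first array set, triangles for the second, and the group mean with its SD. Cholesterol synthesis averaged 8.72 in obese, 9.03 in control and 9.03 in obese-resistant mice, and the obese mouse of the second set lay at 9.33.

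The comparison of obese with obese-resistant mice asks what differed between mice on the same diet that did and did not become obese. Cdk14, a cyclin-dependent kinase (Entrez 18647), averaged 6.87 ± 0.25 in obese (SD, n = 6) and 6.04 ± 0.45 in obese-resistant mice (n = 4). Edrf1, an erythroid regulatory factor (Entrez 214764), averaged 6.13 ± 0.34 and 6.81 ± 0.28. Both genes are dim: the lower mean of each lay below the table median of 6.48 used as the filter. Cdk14 exceeded that value in every obese mouse and in no obese-resistant one. None of the top genes passed. Those with higher values in obese mice were Cdk14 (0.83 ± 0.21, SE), Nhsl2 (0.60 ± 0.16), Irf4 (0.52 ± 0.15), Taf1c (0.50 ± 0.15), Arfgef2 (0.51 ± 0.16) and Stra6, a retinol transporter (0.58 ± 0.19). Those with lower values were Edrf1 (-0.67 ± 0.19), Zfp54 (-0.60 ± 0.17), Lonp1, a mitochondrial protease (-0.52 ± 0.15), Lysmd3 (-0.59 ± 0.18), Tfcp2 (-0.44 ± 0.14) and Agbl3 (-0.65 ± 0.21). For each of these, 6 of 6 obese mice lay on that side of the obese-resistant mean. The block gave 0.41 to 0.80 and -0.62 to -0.40, and each kept its sign within both sets. With limma, 0 of 11867 genes passed (smallest adjusted p = 0.918, 316 with an unadjusted p under 0.05, 268 with the block), array weights gave 2249, and such weights with the block gave 0.

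In obese versus obese-resistant mice 13 lists were called, 7 higher and 6 lower in obese mice, of which 9 were also called with the block in the same direction. Fewer lists were called with the second title number as a random block, as given below. With an estimated correlation none was called, at an adjusted p of 0.668 for each of the 13, and no member passed when adjusted over the list alone. Oxidative phosphorylation had a median of -0.26 (33 of 35 genes lower, adjusted p = 8.99e-05), with Sdha at -0.35 ± 0.17, and the block gave -0.11 (adjusted p = 0.00181). Cholesterol synthesis had a median of -0.29 (16 of 17 lower, adjusted p = 0.00201), with Hsd17b7 at -0.62 ± 0.27 and Msmo1 at -0.34 ± 0.17, and the block gave -0.12 (adjusted p = 0.0158). The cell cycle had a median of -0.21 (29 of 30 lower, adjusted p = 0.00668), with -0.03 under the block (adjusted p = 0.544), and ribosomal proteins, a technical check, -0.13 (20 of 23 lower, adjusted p = 0.0315), with -0.02 under the block (adjusted p = 0.439). In each of these 4 lists, 5 of 6 obese mice lay below the obese-resistant mean. Within the first and second sets the medians were -0.17 and 0.00 for oxidative phosphorylation, -0.27 and 0.06 for cholesterol synthesis, -0.11 and 0.13 for the cell cycle, and -0.05 and -0.04 for ribosomal proteins. The calls of oxidative phosphorylation and cholesterol synthesis held without any 1 array. The cell cycle call ended without obese mouse 2 (adjusted p = 0.106) or obese-resistant mouse 4 (0.0885), and the ribosomal one without obese mouse 1 (0.0651), obese mouse 3 (0.0686), obese-resistant mouse 2 (0.0751) or obese-resistant mouse 3 (0.175). The cell cycle median was -0.12 without obese mouse 2, -0.34 without obese mouse 6, -0.12 without obese-resistant mouse 3 and -0.13 without obese-resistant mouse 4, and the ribosomal one -0.08 without obese-resistant mouse 3.

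Among the 7 higher lists, 5 were not markers of other cells. Dissociation and immediate early genes, fixed as a technical check, had a median of 0.17 (16 of 21 higher, 5 of 6 mice, adjusted p = 0.00251), with Nr4a1 at 0.72 ± 0.23 and Nr4a2 at 0.63 ± 0.27; the block gave 0.19 (adjusted p = 0.000917). Inflammatory and NF-kB genes had a median of 0.15 (11 of 15 higher, 3 of 6 mice, adjusted p = 0.0220), with Tnf at 0.52 ± 0.30, Ccl2 at 0.52 ± 0.26 and Ptgs2 at 0.58, and the block gave 0.16 (adjusted p = 0.0291). NK cytokines and chemokines had a median of 0.04 (11 of 17 higher, 4 of 6 mice, adjusted p = 0.0220), with Il13 at 0.36 ± 0.16 and Ccl3 at 0.58 ± 0.28, and the block gave 0.08 (adjusted p = 0.0383). Tissue-resident NK and ILC1 genes had a median of 0.28 (11 of 12 higher, 5 of 6 mice, adjusted p = 0.00396) and 0.14 with the block (adjusted p = 0.0214). Insulin, leptin and adipokine signalling had a median of 0.06 (12 of 15 higher, 5 of 6 mice, adjusted p = 0.0362), with Insr at 0.38 and Irs2 at 0.35, and 0.08 with the block (adjusted p = 0.0214). Each of these calls except the tissue-resident one ended without obese-resistant mouse 2, at adjusted p = 0.219, 0.299, 0.0751 and 0.322 in the order given. The inflammatory, NK cytokine and insulin calls also ended without obese mouse 1 (0.264, 0.0651 and 0.0651) or obese mouse 4 (0.0832, 0.0632 and 0.111). The inflammatory and NK cytokine calls ended without obese-resistant mouse 1 (0.0554 and 0.0975), the inflammatory one without obese mouse 5 (0.0703) and the insulin one without obese mouse 6 (0.0560). Within the first and second sets the medians were 0.35 and -0.06 for immediate early, 0.36 and -0.26 for inflammatory, 0.20 and -0.07 for NK cytokine, 0.22 and 0.05 for tissue-resident, and 0.18 and -0.04 for insulin signalling genes.

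Leaving out 1 array moved the medians of these 5 lists by over 1.5 times in several cases. The immediate early median was 0.28 without obese-resistant mouse 1 and 0.08 without obese-resistant mouse 2, and the tissue-resident one 0.16 without obese mouse 1 and 0.16 without obese-resistant mouse 3. For inflammatory genes it was 0.03 without obese mouse 1, 0.26 without obese mouse 2, 0.00 without obese-resistant mouse 2, 0.09 without obese mouse 4, 0.10 without obese mouse 5 and 0.26 without obese mouse 6. NK cytokine genes gave 0.07 without obese mouse 2, 0.02 without obese-resistant mouse 2, 0.13 without obese mouse 3, 0.00 without obese mouse 4, 0.07 without obese mouse 5, 0.10 without obese mouse 6, 0.07 without obese-resistant mouse 3 and 0.09 without obese-resistant mouse 4. Insulin signalling gave 0.02 without obese-resistant mouse 2, 0.11 without obese mouse 3, 0.03 without obese mouse 4, 0.13 without obese mouse 5, 0.13 without obese-resistant mouse 3 and 0.15 without obese-resistant mouse 4.

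Markers of other cells moved as well. Macrophage and monocyte markers had a median of 0.29 (11 of 14 higher in obese mice, 3 of 6 mice above the obese-resistant mean, adjusted p = 0.0241), with Fcgr1 at 0.52 and Adgre1 at 0.39, and 0.25 with the block (adjusted p = 0.0427). Dendritic cell and MHC class II markers had a median of 0.31 (9 of 9 higher, 4 of 6 mice, adjusted p = 0.00668), with Xcr1 at 0.66 and H2-DMb1 at 0.54, and 0.23 with the block (adjusted p = 0.0189). Smooth muscle and pericyte markers had a median of -0.46 (7 of 8 lower, 5 of 6 mice, adjusted p = 0.0466), with Actg2 at -1.84 and Acta2 at -1.35, and -0.19 with the block (adjusted p = 0.0816). Trophoblast and fetal markers had a median of -0.35 (6 of 7 lower, 6 of 6 mice, adjusted p = 0.0466), with Peg10 at -1.04 ± 0.42, and -0.27 with the block (adjusted p = 0.124). In the first set the 4 medians were 0.70, 0.54, -0.37 and -0.18, and in the second -0.85, -0.38, 0.16 and -0.49. The macrophage call ended without obese mouse 5 (adjusted p = 0.327), obese mouse 1 (0.209), obese-resistant mouse 1 (0.203), obese-resistant mouse 2 (0.0959) or obese mouse 4 (0.0632), and the dendritic call without obese-resistant mouse 2 (0.167) or obese mouse 1 (0.0651). Of the 20 fits that left out 1 array, 6 kept the smooth muscle call and 10 the trophoblast call, and the highest adjusted p, 0.305 and 0.633, came without obese-resistant mouse 4. The macrophage median was 0.15 without obese mouse 1, 0.11 without obese-resistant mouse 1, 0.11 without obese mouse 5 and 0.45 without obese mouse 6, the dendritic one 0.12 without obese mouse 1 and 0.51 without obese mouse 6 and the smooth muscle one -0.29 without obese mouse 3. Trophoblast markers gave -0.61 without obese-resistant mouse 1, -0.20 without obese mouse 3, -0.53 without obese mouse 6 and -0.20 without obese-resistant mouse 4.

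The comparison of the high-fat diet with the control diet asks how the mean of both groups on that diet differed from control, so that 1 of the groups can carry a difference. Fgl2, a secreted immune regulator (Entrez 14190), averaged 10.17 ± 0.20 in obese (SD, n = 6), 10.17 ± 0.06 in obese-resistant (n = 4) and 9.81 ± 0.20 in control mice (n = 10). Hmgn1 averaged 6.78 ± 0.18, 6.84 ± 0.21 and 7.26 ± 0.23, and every mouse on the high-fat diet lay on that side of the control mean for both genes. Genes with higher values were Fgl2 (0.36 ± 0.10, SE), Homer3 (0.51 ± 0.14), Pdcd1 (0.66 ± 0.19), Rgs18 (0.46 ± 0.14), Enpp5 (0.41 ± 0.13) and Slc25a36 (0.43 ± 0.14), seen in 8 to 10 of 10 mice. Lower values were found for Hmgn1 (-0.46 ± 0.11), Prr14l (-0.48 ± 0.12), Dclre1a (-0.52 ± 0.13), Scp2 (-0.60 ± 0.18), Tacc2 (-0.40 ± 0.12) and Gm3448 (-0.50 ± 0.17), seen in 9 or 10 of 10 mice. With the block they were 0.32 to 0.61 and -0.57 to -0.34, and within the sets the signs were the same except for Slc25a36 in the second (-0.13). With limma, 0 of 11867 genes passed (smallest adjusted p = 0.9999, 186 with an unadjusted p under 0.05, 329 with the block), and array weights also gave 0. Pdcd1 passed among the 13 inhibitory receptor genes, adjusted over the list alone (adjusted p = 0.0246, higher in 8 of 10 mice), and with the block it did not (adjusted p = 0.0508, 0.61 ± 0.19). It was the only member to pass in this way over the 35 lists of each of the 4 comparisons. This adjustment does not cover the number of lists and comparisons, so chance is not excluded for it.

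For the high-fat diet 5 lists were called, none of them with the block or with an estimated correlation (adjusted p = 0.857 for each). For cholesterol synthesis and the cell cycle the obese-resistant medians against control were near 0, as given above. The obese medians against control were -0.30 and -0.29, and with the block -0.23 and -0.002. Most obese mice were in the first array set, so these medians do not separate obesity from the array sets. Lower lists were cholesterol synthesis (median -0.18, 15 of 17 genes lower, 7 of 10 mice below the control mean, adjusted p = 0.00587), the cell cycle (-0.12, 26 of 30 lower, 7 of 10 mice, adjusted p = 0.00602), with Kif11 at -0.40 ± 0.15, and decidual stromal markers (-0.25, 16 of 17 lower, 8 of 10 mice, adjusted p = 0.00852), with Hoxa11 at -0.45 ± 0.21. Higher lists were the interferon response (0.08, 17 of 23 higher, 6 of 10 mice, adjusted p = 0.0309), with Usp18 at 0.23 ± 0.13, and T cell markers (0.20, 8 of 10 higher, 6 of 10 mice, adjusted p = 0.0309). With the block the 5 medians were -0.08, 0.03, -0.01, 0.14 and 0.20 in the order given. Within the first set they were -0.07, 0.04, 0.06, 0.18 and 0.18, and within the second 0.07, 0.09, -0.15, -0.02 and 0.09. The cholesterol call held without any 1 array, and 17, 16, 9 and 11 of the 20 such fits kept the others. The highest adjusted p was 0.103 for the cell cycle (without control mouse 3), 0.166 for decidual markers and 0.288 for T cells (each without obese-resistant mouse 1), and 0.305 for interferon genes (without control mouse 1). Medians moved by over 1.5 times for cholesterol synthesis (-0.12 without control mouse 3 and -0.12 without control mouse 8) and T cell markers (0.11 without control mouse 3 and 0.13 without control mouse 9). For the cell cycle they were -0.20 without control mouse 2, -0.08 without obese-resistant mouse 1, -0.07 without obese-resistant mouse 2, -0.07 without control mouse 3, -0.20 without obese mouse 6, -0.19 without obese-resistant mouse 4 and -0.19 without control mouse 9. The interferon median was 0.02 without control mouse 1, 0.04 without obese mouse 1, 0.12 without obese-resistant mouse 2, 0.05 without control mouse 3, 0.14 without control mouse 5, 0.04 without obese-resistant mouse 4 and 0.04 without control mouse 9. Decidual markers gave -0.10 without obese-resistant mouse 1, -0.14 without control mouse 4, -0.16 without control mouse 6 and -0.42 without obese-resistant mouse 4.

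Whether the obese and obese-resistant groups shared a response was measured as the correlation, across genes, of their differences from separate sets of 5 control mice, so that no control was used on both sides. It averaged -0.18 over 100 splits of the controls (SD over splits 0.20), and -0.02 after the array set was removed. Genes are not independent replicates. With all 10 controls on both sides the correlation was 0.14, and simulated groups without any change gave 0.33, since shared controls alone produce a positive value. The simulated arrays held no array sets, while the real ones did, so these values do not compare directly. The value with the set removed as well is given with the alternatives below. A shared response was therefore not detectable with these arrays.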

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

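The comparisons of array sets, the block by array set, the redraws within the sets, the control probe tests and the tests on genes called with array weights were chosen after the results were seen, while the search for far samples and the counts over other splits of the mice were planned.

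Several genes and list means had 1 mouse far from the others of its group. Of 396 sets of values tested, for 97 genes and 35 lists in 3 groups, 22 had such a mouse, and chance alone gives about 1 in 20, or 19.8. Among control mice these were Scp2 at 7.94 in control mouse 4 (others 6.66 to 7.28), Stra6 at 7.97 in control mouse 10 (6.95 to 7.44), Sqle at 7.91 in control mouse 9 (8.79 to 9.30), Igf2 at 9.31 in control mouse 5 (7.58 to 8.17) and the insulin signalling mean at 8.90 in control mouse 2 (9.12 to 9.29). Among obese mice they were Pgf at 7.90 in obese mouse 5 (6.68 to 7.07), Peg10 at 4.96 in obese mouse 2 (5.63 to 6.00) and Hk2 at 7.80 in obese mouse 3 (8.29 to 8.53). Obese mouse 6, the one obese mouse of the second array set, held 6 of the 22: Lss at 9.41 (8.23 to 8.62), Inpp4b at 10.07 (11.16 to 11.64), Scd1 at 7.05 (6.15 to 6.44), and the means of the cytotoxic granule at 10.86 (10.48 to 10.62), cholesterol synthesis at 9.33 (8.49 to 8.77) and decidual stromal markers at 7.68 (6.71 to 7.06). Obese-resistant mouse 2 held another 6: Slx4ip at 5.70 (6.94 to 6.97), Cenpf at 6.57 (7.02 to 7.06), Oasl1 at 5.71 (6.70 to 6.85), and the means of insulin signalling at 8.81 (9.14 to 9.16), immediate early genes at 8.98 (9.46 to 9.48) and dendritic cell markers at 8.31 (8.67 to 8.71). The remaining ones were Peg10 at 8.31 in obese-resistant mouse 4 (6.02 to 6.35) and Cd8a at 7.78 in obese-resistant mouse 1 (6.90 to 6.997).

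Between obese and obese-resistant mice, both on the high-fat diet, 13 lists were called by the camera test given in the report, at the preset correlation. As many lists came from 17 of 100 splits of these mice, so chance is not excluded. The median differences were 0.28 for tissue-resident NK and ILC1 genes, 0.042 for NK cytokines, -0.26 for oxidative phosphorylation, -0.29 for cholesterol synthesis, -0.21 for the cell cycle, 0.15 for inflammatory genes, 0.064 for insulin signalling, -0.13 for ribosomal proteins, 0.17 for immediate early genes, -0.35 for trophoblast, -0.46 for smooth muscle, 0.29 for macrophage and 0.31 for dendritic cell markers. With the correlation estimated for each list, 0 of the 35 were called. With the array set as a block 9 of the 13 were called, and the cell cycle, ribosomal, trophoblast and smooth muscle calls ended (adjusted p = 0.544, 0.439, 0.124 and 0.0816 by camera, with medians of -0.03, -0.02, -0.27 and -0.19).

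The first pattern weighed is that 6009 of 11867 genes differed between the array sets. A narrower signal range in the first set is argued against as the whole cause, since 79.6% of these genes still differed in the same direction after cyclic loess scaling, which moved the median difference of all genes from 0.14 to 0.00. More decidual stromal cells in the second set, after the sort by flow cytometry, remain a candidate source. Of 17 markers, 14 passed as higher there and 1, Wnt4 (-0.51), as lower. The abundant markers Prl8a2 (8.69 to 10.74), Gja1 (7.98 to 8.94) and Igfbp5 (6.78 to 8.89) were among the higher ones. None of the 17 markers is in another list, and 49.8% of the genes still differed with the markers' mean in the fit. NK identity genes did not change alike: 9 of 16 differed relative to their list mean (Ncr1 by 0.40, Klrc1 by -1.25). Centring by itself puts genes on either side. Without centring 4 were higher and 5 lower. The counts were 6 and 2 with arrays shifted to 1 median, and 2 and 3 with the decidual markers in the fit. After cyclic loess 7 were lower and 2 higher, Fcgr3 (1.22) and Nfil3 (0.38), while Ncr1 (0.17) and Eomes (0.15) no longer differed. Whether cells other than NK cells express some of these genes was not tested. The counts therefore do not decide whether the share of NK cells was lower. A difference in handling may contribute, because the poly-A controls, which come from no cell, averaged 9.88 in the first and 8.73 in the second set (exact permutation p = 0.00138). Hybridisation controls averaged 11.19 and 10.44 (exact permutation p = 0.000286). Background probes of high GC content averaged 7.43 and 7.99 (exact permutation p = 0.000988). The step at which the sets parted was not tested. The labels name no group that matches the sets. The second title number, however, parts the arrays in the same way. It was lower in every array of the first set than in any array of the second. What either title number means is not given. Apart from cell composition no biological explanation was tested, and a difference between 2 cohorts of mice also stays open.

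The second pattern is the 9 lists called in obese versus control, where 5 of 6 obese and 4 of 10 control mice were in the first set. The imbalance may account for much of the tissue-resident, oxidative phosphorylation, cell cycle, ribosomal and decidual differences: their medians of 0.20, -0.17, -0.29, -0.11 and -0.23 were 0.0946, -0.0214, -0.00235, 0.0345 and 0.0537 with the set as a block, where none was called, and groups redrawn within the sets called them in the same direction in 29, 57, 75, 51 and 40 of 99 redraws. In simulated genes that vary independently, the imbalance alone gave medians of 0.17, -0.16, -0.24, -0.12 and -0.34 for these lists (called in 4, 6, 50, 5 and 6 of 100 draws), -0.20 for cholesterol synthesis (1), -0.18 for trophoblast (0), 0.10 for T cells (2) and -0.05 for interferon genes (0), with at most 3 lists per draw (median 1, real 9), so outside the cell cycle variation that genes share between mice may add to it. For the interferon response the imbalance is argued against: the block raised its median from 0.14 to 0.21 and kept the call, and redraws within the sets, which keep the imbalance, had a median of 0.00, while chance stays open, since such redraws with the block called the list in 21 of 99. Macrophage marker medians had the same signs as this list within the sets (0.33 in the first and -0.90 in the second). Their part in the interferon difference was not weighed. For cholesterol synthesis (-0.30 and, with the block, -0.23, still called; redraws -0.23, and 17 of 99 called with the block), trophoblast (-0.36 and -0.21) and T cell markers (0.20 and 0.19), the set, obesity and differences between single mice cannot be told apart.

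The third pattern is the genes called with array weights, 1783 in obese versus control and 2249 in obese versus obese-resistant mice. Such weights may have turned the set difference into a group difference, since 99.7% and 99.2% of the called genes had the direction that the set difference predicts, against 85.6% and 84.5% of all genes. The second set held 60% of the control arrays and 84.4% of their weight, 50% and 86.0% for obese-resistant mice, and 16.7% and 7.68% for obese mice. With the block and a weight per array, limma called 0 genes in both comparisons, with 194 and 240 at an unadjusted p under 0.05.

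Other splits of the mice into groups of the same sizes, 100 for each comparison with the real one included, do not exclude chance for the list counts. As many lists as the real 9 in obese versus control came from 28 splits (highest other 18), as many as the 1 in obese resistant versus control from 91 (17), as many as the 13 in obese versus obese resistant from 17 (22), and as many as the 5 for the high-fat diet from 59 (19). The splits with the most lists parted the sets by 16.7, 25, 8.33 and 10 percentage points, against 43.3, 10, 33.3 and 30 in the real groups. In these top splits the imbalance was thus smaller than in the real groups, except in obese resistant versus control. How list counts relate to the imbalance over all splits was not tested. Since these splits ignore the array sets, the counts with the block were set against splits within the sets: as many as the real 2, 1 and 10 lists in the first 3 comparisons came from 83 of 100, 95 of 100 and 19 of 63 splits (highest other 20, 21 and 19), so chance is not excluded there either. For the high-fat diet the block left 0 lists, which such splits cannot test.

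For genes the real count by limma was 0 in each comparison, so 100 of 100 splits give as many by construction, and this says nothing about chance (499, 83, 316 and 186 genes had an unadjusted p under 0.05, and array weights gave 1783, 0, 2249 and 0). The highest counts in other splits were 2882, 3796, 0 and 0 in the same order. The splits with 2882 and 3796 genes differed in the share of the sets by 70 and 80 percentage points, which points to the array sets as a structure of the samples.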

How the results depend on the processing

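The alternatives that use the array set, its weights or the 3 least correlated arrays were chosen after the data were seen, and the others were planned. Arrays have no read depth, and the limit is signal over background: a gene below the table median of 6.48 in 17 or more arrays was not tested, and of the genes changed 1.5-fold in the simulated data, the smallest change tried, 22% to 46% were recovered across the comparisons. Where a result below did not hold and no reason is given, the cause was not tested.

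The count of 0 genes was the same in each of the 4 comparisons under every alternative except array weights, with 1783 genes in obese versus control and 2249 in obese versus obese resistant, and testing all 16429 probe sets, named or not, with 1 in obese versus control. That probe set is a negative control without a gene (1.09 ± 0.17, adjusted p = 0.0463, higher in 6 of 6 mice; with the block 1.02, adjusted p = 0.222). Leaving out each mouse in turn gave 0 to 0 genes.

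The list counts, 9, 1, 13 and 5 in the order of the comparisons in the report, depended on more choices. With the correlation estimated for each list they were 0, 0, 0 and 0, and with the block as well 0, 0, 0 and 0. The block alone gave 2 in obese versus control and 0 for the high-fat diet, where the imbalance of the sets is a candidate explanation. The block with weights by set gave 0 in obese versus control, 3 in obese versus obese resistant and 0 for the high-fat diet, and with a weight per array 2, 0, 1 and 1. The first set alone gave 3 in obese versus control, 0 in obese resistant versus control and 0 for the high-fat diet, and the second alone, with 1 obese mouse, 0 in obese resistant versus control and 8 in obese versus obese resistant; both have fewer arrays. Without control mouse 2, control mouse 9 and obese-resistant mouse 2, the counts were 7 in obese resistant versus control, 5 in obese versus obese resistant and 8 for the high-fat diet.

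Among planned choices, the stricter filter, which leaves fewer genes, gave 5 in obese versus control and 2 for the high-fat diet. Quantile normalization gave 3 for the high-fat diet. Array weights gave 0 in obese resistant versus control and 11 for the high-fat diet. The second title number as a random block, with a consensus correlation of 0.374 between mice that share it, gave 6 in obese versus obese resistant. That block ended 9 of the 28 list calls over all comparisons. Mice that share a second title number always lie in the same array set, and the correlation was estimated without the set in the fit. It can therefore include the set difference. The first title number as a covariate gave 5, 2 and 3 in the first 3 comparisons. Decidual markers in the fit gave 5 in obese versus control and 0 for the high-fat diet, and macrophage markers 3 in obese resistant versus control and 8 in obese versus obese resistant. Counts within 1.5 times the reported ones came with no filter, arrays shifted to 1 median and the trend and robust variance model.

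Leaving out each mouse in turn gave 4 (without obese mouse 1) to 17 lists (without obese mouse 3) in obese versus control. In obese resistant versus control it gave 0 (without obese-resistant mouse 2) to 3 (without control mouse 1, 9 or 10 or obese-resistant mouse 1 or 4), with 2 without control mouse 3. In obese versus obese resistant it gave 4 (without obese-resistant mouse 2) to 15 (without obese-resistant mouse 3), with 6 without obese mouse 1 and 7 without obese mouse 4. For the high-fat diet it gave 1 (without obese-resistant mouse 1) to 8 (without obese-resistant mouse 2 or control mouse 5), with 2 without control mouse 3 or 4 and 3 without control mouse 1 or 8, obese mouse 1 or 4, or obese-resistant mouse 3.

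In the second set alone, 5 called lists had the opposite direction; each rests on obese mouse 6, the 1 obese mouse there, and its spread is assumed to be that of the other groups: the cell cycle in obese versus control (0.16) and in obese versus obese resistant (0.13), and inflammatory genes (-0.26), macrophage markers (-0.85) and dendritic cell markers (-0.38) in the latter. Of 28 list calls, 16 ended with the block and 28 with an estimated correlation. Of 602 named gene values, none passing, the direction flipped for 45 with the block, 55 in the first set alone, 205 in the second alone and 18 with array weights. The shared response, -0.18, was 0.14 with all 10 controls on both sides and 0.34 with the array set removed as well. Shared controls add a positive value to both, which was 0.33 in simulated groups without any change or array sets. Without 1 mouse the shared response ran from -0.36 (obese-resistant mouse 2) to 0.0573 (obese-resistant mouse 4).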

Other observations

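The observations below were chosen after the values were seen, and no test of the spread between single mice was run. Markers of some other blood cells varied widely between single mice. The mean of the erythroid markers ran from 6.70 in obese mouse 2 to 10.54 in obese mouse 5, a range of 3.84 on the log2 scale, with group means of 8.93 in control, 8.67 in obese and 9.60 in obese-resistant mice. Mast cell markers ran from 6.14 in obese mouse 2 to 8.56 in obese mouse 5, macrophage markers from 7.09 in control mouse 1 to 9.11 in obese mouse 5, and neutrophil markers from 6.05 in control mouse 1 to 8.90 in obese mouse 1.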
